A study of Homo sapiens with 2 samples.

How the data were processed

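The measurements were in situ transcript counts from Xenium, a 10x Genomics imaging assay in which barcoded probes against a fixed gene panel are decoded on a tissue section and each decoded transcript is assigned to a segmented cell. Per the labels' protocols, unfixed frozen postmortem human dorsolateral prefrontal cortex (dlPFC) was cryosectioned at 10 µm in the coronal plane, after fluorescent in situ hybridization had shown that the blocks ran from layer 1 to the white matter, and a 266-gene human brain panel was hybridized. The 2 samples were 2 slides of dlPFC, called slide 1 and slide 2. Per the series' design text, each slide carried tissue of 3 donors, 4 donors contributed in all, and adjacent sections of 2 donors lay on both slides. A map from cells to donors and cell positions were not used here, so each slide was 1 replicate (n = 2), the slides were not independent, and every p-value measures the spread between these slides only. The labels give 1 group, so no contrast between conditions was made.

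For each slide the authors deposited raw transcript counts per feature and segmented cell as a sparse matrix of whole numbers, which the file headers give as integers, together with a list of cell identifiers and a list of features. No normalization had been applied to these counts. The decoding and segmentation software, its version and its transcript quality threshold were not given in the sources used here. The 541 features were 266 genes, 20 negative control probes, 41 negative control codewords, 207 unassigned codewords and 7 deprecated codewords. Only the 266 genes entered library sizes and tests; they held 97.7% of all counts on slide 1 and 97.8% on slide 2. Gene symbols and Ensembl identifiers are those the deposited feature lists pair. No genome build was given in the sources used here, and no coordinates are printed.

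Cells with at least 20 panel transcripts were kept, which left 159685 of 160995 cells on slide 1 and 155171 of 157073 on slide 2. A doublet caller was not run, because segmented cells are not droplets; cells that overlap or lie side by side in a section can still share transcripts. Cells of both slides were clustered on 56 anchor genes, the panel members of marker lists for cell classes and neuronal subclasses. The other 210 genes were held out of the clustering, so that tests between classes used genes that had not formed the clusters. They still had a part in the naming, because the 10 leading genes of a cluster were drawn from the whole panel. Anchor counts were scaled to the median total per cell, log1p-transformed and reduced to 25 principal components. Each cell was joined to its 15 nearest neighbours, found exactly, with links weighted by the overlap of neighbour lists (Jaccard index), and the graph was split by Leiden clustering at resolution 1 with 2 iterations (igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). A first version with approximate neighbours came out differently on another type of processor; after its results had been seen it was replaced by this one, which works in whole-number steps, 1000 to a unit of the log scale. A cluster took the name of a class only if at least 3 markers of that class reached 1.5-fold over all other cells, its 10 leading genes all reached 2-fold, and no other class led among them or had 3 clear markers. Clusters that failed stayed unnamed. The limit of 3 clear markers was not applied between oligodendrocytes and their precursors. Between excitatory and inhibitory neurons a rival could pass it if fewer of its markers reached 1.5-fold. The marker lists were fixed before the data were examined, as were the tests, gene lists and alternatives; the thresholds of the naming rule were set after the clusters had been seen, and 2 further fits (of the cluster led by FLT1 and PECAM1 and of the astrocyte clusters), 2 more seeds for the clustering and the tests named as such were chosen later. Only 2 endothelial and 2 mural or fibroblast markers were on the panel, so no vascular class could be named, and no cluster met the rule for lymphocytes. Upper-layer, middle-layer and VIP markers on the panel also numbered 2 each, and those clusters are called by those markers.

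Counts were summed per slide and class, or per slide and subclass, and held-out genes were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), each class against the mean of the others, with slide as a block and the total panel count of each sum as library size. Genes needed at least 10 counts in at least 2 sums, which all 210 held-out genes met. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in size. Residual degrees of freedom were 5 for the classes, 2 for excitatory and 3 for inhibitory subclasses, and the common biological coefficient of variation was 6.20%, 9.62% and 4.54%. Total scaling was preferred because a panel picked for cell types leaves few unchanging genes; fold changes are therefore relative to the panel total of a class. Simulated counts were drawn from 1 profile, pooled over the groups of a fit, with some genes raised in 1 group. All 20 genes raised 3-fold were called in each of the 5 fits and none of the 170 unchanged genes was. Because all other genes kept 1 level, false calls under the wider differences of the real data were not measured. Genes raised 1.5-fold lie under the fold threshold, and 0 of 20 were called. The raised genes shifted the total, so between 44 (the classes and the excitatory subclasses) and 117 (the classes with the cluster led by FLT1 and PECAM1) of the 170 unchanged genes passed the adjusted p alone in the simulations, and a call therefore rested on the fold threshold as well. With no gene changed, 0 genes passed.

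For each class and subclass the text names the 3 called genes with the largest positive log2 fold change, provided they were higher on each slide and reached 0.1 transcripts per cell in the class on both; for deep-layer-like against LAMP5- and CUX2-high cells it names 5 in each direction, and between slides 5 in each direction among genes with at least 1000 transcripts. Members of the gene lists and anchor genes may be named too. The 9 lists covered astrocyte-associated genes, microglia and macrophage state, vascular and extracellular matrix genes, lymphocyte-associated genes, cell cycle, amyloid precursor and gamma-secretase, myelinating oligodendrocyte-associated genes, progenitor-associated genes, and neuronal synapse and excitability; they were counted over members that were on the panel and not anchors. CD83 stands in both the microglia and lymphocyte lists and NES in both the astrocyte and progenitor lists.

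Slides were compared as 1 library each, with no test: CPM of summed panel counts, the ratio with an exact 95% interval, and genes at least 1.5-fold apart. Intervals of shares are exact binomial at 95%. Intervals cover counting error only. In a simulation with 200 genes changed 2-fold, 199 were recovered and 95.1% of intervals held the true ratio. Non-negative matrix factorization (rank 20, log1p of counts scaled to the median total, at most 200 iterations, tolerance 0.0001) was fitted to each slide, factors were paired by cosine similarity of gene loadings, called matched at 0.8 or more, and projected on the other slide by non-negative least squares; on simulated data 10 of 10 known factors were recovered. The simulated sets were fitted at their true rank of 10, and transferred factors explained 99.6% of them. Recovery there does not measure how reliable the factors of the real counts are. Both rank-20 fits stopped at the iteration limit. numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

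Alternatives were edgeR's TMM scaling, DESeq2 1.42.0 with its size factors, scaling to the number of cells, no filter on low counts, no slide block, leaving out each slide of a class in turn (the remaining sum is then assumed to vary like those of the other classes), filters of 10 and 50 transcripts per cell, Leiden resolution 2, Leiden seeds 2 and 3 in place of 1, k-means with 40 clusters, clustering on all panel genes, a 2-fold threshold between slides, ranks 10 and 30, counts without log, and a cosine of 0.9. Slide 1 held 57307600 panel transcripts and slide 2 held 48183894.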

Results

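Transcripts of 266 genes were counted in segmented cells of human dlPFC on 2 Xenium slides. Slide 1 held 160995 cells and 57307600 panel transcripts, with a median of 310 transcripts (interquartile range 182 to 476) and 91 genes per cell. Slide 2 held 157073 cells and 48183894 panel transcripts, with a median of 254 transcripts (138 to 417) and 82 genes per cell. Filtering at 20 transcripts removed 1310 cells (0.814%) from slide 1 and 1902 (1.21%) from slide 2. The series concerns the transfer of non-negative factors between data sets, and the tissue blocks were picked to hold all cortical layers. The comparisons below therefore ask which genes separated cell classes and laminar subclasses, how far the slides differed, and how well factors carried over from one slide to the other.

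Neurons, glia and microglia were all recovered on both slides. Excitatory neuron-like cells, which release glutamate, made up 18.95% of cells on slide 1 and 19.98% on slide 2 (19.5% ± 0.731, SD, n = 2). Inhibitory neuron-like cells, which release GABA, made up 10.4% and 9.20% (9.82% ± 0.880). Oligodendrocyte-like cells, the myelin-forming glia, were at 12.96% on slide 1 and 17.05% on slide 2 (SD 2.89), and microglia- or macrophage-like cells, the resident immune cells, at 5.48% and 4.25% (4.87% ± 0.872). The 2 oligodendrocyte-like clusters went opposite ways. The one led by MAG and KLK6 went from 5.56% to 10.7%, with a median of 247 transcripts per cell on slide 1 and 137 on slide 2. The one led by CNDP1 and CDH1 went from 7.40% to 6.35%, with medians of 337 and 290. Control probes, summed over all 20, stood at 1172 and 1227 CPM in the MAG-led cluster and at 390 and 507 CPM in the CNDP1-led one. Astrocyte-like cells (12.9% ± 0.199) and oligodendrocyte precursor-like cells (OPC-like, 3.47% ± 0.0133) had similar shares on both slides. Inhibitory cells were 35.5% of neurons on slide 1 (95% exact binomial interval 35.1 to 36.0) and 31.5% on slide 2 (31.1 to 31.9), a mean of 33.5% ± 2.83 (SD, n = 2); the slides differed by more than counting error, and with 1 value per slide no test was made. Clustering on all panel genes, in place of the marker genes alone, put this mean at 47.1%, because the excitatory neuron-like share was then 10.0% on slide 1 and 11.6% on slide 2 while the inhibitory share stayed at 10.3% and 8.93%, and 45.2% of cells (mean of the slides) had no class name. In the reported clustering the inhibitory shares leave out an unnamed cluster led by RELN, CXCL14 and VIP, with 2.35% of cells on slide 1 and 1.53% on slide 2.

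Of the 23 clusters, those without a class name held 36.0% of cells on slide 1 and 33.0% on slide 2. The largest was led by FLT1 and PECAM1, both endothelial genes, with 13.42% of cells on slide 1 and 11.97% on slide 2. A cluster led by MOG, HS3ST2 and CAPN3 mixed oligodendrocyte and neuronal genes (11.5% and 11.7%). Clusters led by S100A4 and CAV1 (4.20% and 3.78%) and by ADAMTS12 and CD163, a scavenger receptor of macrophages (3.63% and 3.01%), had medians of only 103 and 90 transcripts per cell. A cluster led by RELN, CXCL14 and VIP, all genes of interneurons, held 2.35% and 1.53%, a cluster led by CCL5, IL7R and NKG7, genes of lymphocytes, held 0.845% and 0.922% with a median of 46 transcripts, though these 3 genes lay under the brightest control probe on both slides and control probes reached 972 and 1775 CPM in it, and the last held 243 cells.

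**Figure D1:**
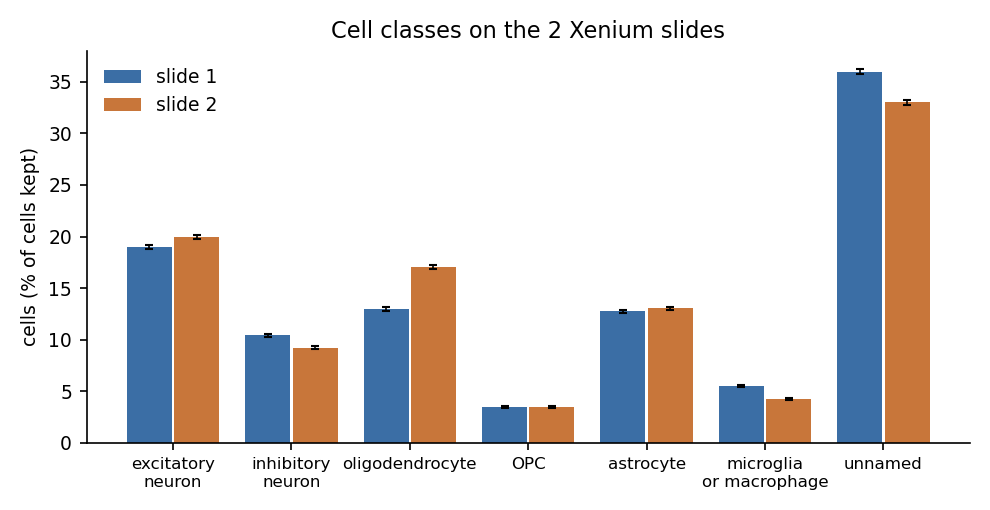
Share of cells in each class (percent of cells kept, vertical axis) on slide 1 and slide 2; bars start at 0 and the error bars are 95% exact binomial intervals, which cover counting error only. Oligodendrocyte-like cells stood at 12.96% on slide 1 and 17.05% on slide 2, and astrocyte-like cells at 12.74% and 13.02%.

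Transcripts of class markers were also counted in cells of other classes, a measured fact that bears on every fold below. SLC17A7, the vesicular glutamate transporter of cortical excitatory neurons, averaged 44.2 transcripts per excitatory cell and 10.8 to 17.1 per cell in the other classes, or 24.4% to 38.6% of the excitatory level. AQP4, the astrocyte water channel, averaged 27.7 in astrocytes and 5.37 to 8.81 elsewhere. The levels outside the own class were relatively lower for GAD1, which makes GABA (27.2 against 1.12 to 3.70), for MOG, a myelin protein (4.89 against 0.348 to 0.717), for PDGFRA in OPC-like cells (12.7 against 0.495 to 1.27) and for P2RY12 in microglia (10.4 against 0.432 to 0.599).

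Excitatory neurons were marked among held-out genes by ADAMTS16 (ENSG00000145536), a secreted metalloprotease, FSTL4 (ENSG00000053108), a follistatin-like protein, and NPY1R (ENSG00000164128), a receptor for neuropeptide Y. ADAMTS16 was higher by 3.01 ± 0.05 on the log2 scale (SE), with 0.567 ± 0.0945 transcripts per cell (SD, n = 2 slides) against 0.0606 ± 0.00449 in inhibitory neurons, the next class. FSTL4 was higher by 2.30 ± 0.04, with 6.71 ± 0.719 transcripts per cell, and NPY1R by 2.27 ± 0.03, with 5.21 ± 0.806. Of the synapse and excitability list, 8 of 10 measured genes were higher and 1 lower, with the same counts adjusted over the list alone. Among them HTR2A, a serotonin receptor, was higher by 1.87 ± 0.03, KCNH5, a potassium channel, by 1.75 ± 0.04, and CCK, a neuropeptide, by 1.42 ± 0.03. ADRA1A, an adrenergic receptor, was lower (-1.07 ± 0.04), though under the fold threshold with scaling to cell number (-0.43).

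Members of the amyloid, cell cycle and matrix lists were also higher in excitatory neurons, though not the lists as a whole. Of 5 amyloid precursor and gamma-secretase genes, APP, the amyloid precursor itself, rose by 1.02 ± 0.03 and PSEN2, a catalytic subunit of gamma-secretase, by 1.53 ± 0.03, and adjusting over the list alone gave the same 2; without the slide 2 excitatory sum APP stood at 0.995, just under the fold threshold. Of 6 cell cycle genes, 3 were higher, also when adjusted over the list alone: CCNA1 (1.80 ± 0.05), CCNB2 (1.15 ± 0.07) and CENPF (1.17 ± 0.07). CCNB2 had fewer counts on both slides than the brightest negative control probe. In the vascular and extracellular matrix list, 5 of 13 genes were higher and 1 lower, with COL12A1, a collagen, at 1.46 ± 0.05 and CEMIP, a hyaluronan-degrading protein, at 1.49 ± 0.05, and the list alone gave the same counts.

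In inhibitory neurons the named genes were LYPD6B (ENSG00000150556), a modulator of nicotinic receptors, NDST4 (ENSG00000138653), an enzyme of heparan sulfate synthesis, and NXPH2 (ENSG00000144227), a neurexophilin that binds neurexins. LYPD6B was higher by 3.68 ± 0.05 (SE), with 0.942 ± 0.0603 transcripts per cell (SD, n = 2) against 0.105 ± 0.00542 in excitatory neurons. NXPH2 was higher by 3.37 ± 0.07, with 1.58 ± 0.152 per cell. NDST4 was higher by 3.57 ± 0.06 but rare, at 0.240 ± 0.00025 per cell, and on slide 2 its total lay under that of the brightest control probe. Of the synapse and excitability list, 4 of 10 genes were higher, also adjusted over the list alone, including ADRA1A, which rose by 1.495 ± 0.03. Of the matrix list 6 of 13 were higher and 1 lower, with the same counts over the list alone; SULF1, which edits heparan sulfate outside the cell, rose by 2.81 ± 0.11 and POSTN, a matrix protein, by 2.76 ± 0.09. The growth factor receptor EGFR, of the progenitor list, stopped just short of the fold threshold (0.99 ± 0.05), and 0 of that list's 4 measured genes were called.

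Excitatory neurons had 61 of 210 held-out genes higher and 59 lower than the mean of the other classes, with a highest adjusted p among calls of 4.84e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg). Inhibitory neurons had 48 higher and 35 lower, with a highest adjusted p of 9.30e-06 in the same edgeR test. Both splits moved when sums were scaled to cell number, which raised the median of all genes by 0.65 and 0.35 on the log2 scale: excitatory neurons then had 87 higher and 19 lower, and inhibitory neurons 61 and 14.

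Oligodendrocytes carried the myelin program. CLDN11 (ENSG00000013297), the claudin of myelin tight junctions, was higher by 4.71 ± 0.04 on the log2 scale, with 6.21 ± 1.90 transcripts per cell (SD, n = 2) against 0.388 ± 0.0303 in OPC-like cells. CNDP1 (ENSG00000150656), a carnosine-cleaving dipeptidase, was higher by 4.56 ± 0.05 (8.91 ± 2.79 per cell) and KLK6 (ENSG00000167755), a serine protease, by 4.51 ± 0.07 (0.355 ± 0.0990 per cell). All 10 measured genes of the myelinating oligodendrocyte list rose, also adjusted over the list alone, among them MYRF, a transcription factor of myelin genes (4.43 ± 0.06), ST18 (3.72 ± 0.08) and ERBB3, a neuregulin receptor (3.48 ± 0.06). In all, 18 genes were higher and 26 lower, with a highest adjusted p of 4.67e-06 (edgeR, Benjamini-Hochberg). DESeq2 gave 22 and 21. With scaling to cell number, which shifted the median of all genes by -0.49, 15 were higher and 95 lower; oligodendrocyte-like cells had a median of 297 transcripts on slide 1 and 190 on slide 2, against 511 and 431 in excitatory cells.

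OPC-like cells, the dividing precursors of oligodendrocytes, stood apart by GPNMB (ENSG00000136235), a transmembrane glycoprotein placed on the microglia list here. It was higher by 4.52 ± 0.09 on the log2 scale, with 6.23 ± 1.31 transcripts per OPC-like cell (SD, n = 2) against 0.436 ± 0.0804 per microglia- or macrophage-like cell, the next class; in microglia its fold change was 0.30 ± 0.11 and was not called. ATP2C2 (ENSG00000064270), a calcium pump of the secretory pathway, was higher by 2.94 ± 0.07, and CALCRL (ENSG00000064989), a receptor subunit for calcitonin gene-related peptide and adrenomedullin, by 2.91 ± 0.05. Of 4 progenitor genes, SOX4 (2.36 ± 0.03) and SOX11 (1.19 ± 0.05), transcription factors of immature neural cells, rose, also adjusted over the list alone, while EGFR (0.53 ± 0.05) and NES (0.41 ± 0.04) were under the fold threshold. TOP2A, a topoisomerase of dividing cells, was the 1 cell cycle gene called of 6 (2.09 ± 0.10), but with 0.0350 transcripts per cell and a total below the brightest control probe on both slides. On slide 2 its total of 1404 counts did not exceed the mean per control probe. In all, 18 genes were higher and 10 lower, with a highest adjusted p of 7.99e-05 (edgeR, Benjamini-Hochberg); TMM scaling gave 18 and 4.

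Astrocytes were marked by RYR3 (ENSG00000198838), a calcium channel of the endoplasmic reticulum, SPON1 (ENSG00000262655), an extracellular matrix protein, and FBLN1 (ENSG00000077942), a fibulin. RYR3 was higher by 2.96 ± 0.04 on the log2 scale, with 3.41 ± 0.477 transcripts per cell (SD, n = 2) against 0.778 ± 0.0895 in excitatory neurons. SPON1 was higher by 2.81 ± 0.03 (6.602 ± 0.383 per cell) and FBLN1 by 2.59 ± 0.04 (1.83 ± 0.0253 per cell). Of 8 astrocyte-associated genes 7 rose, also over the list alone, including WIF1, a secreted Wnt inhibitor (2.43 ± 0.04), HES1, a target of Notch signalling (1.87 ± 0.05), and SOX2, a transcription factor of neural progenitors and astrocytes (1.69 ± 0.03); NES did not pass the fold threshold (-0.23 ± 0.04). APP was the 1 amyloid gene lower of 5 (-1.11 ± 0.03), and both DESeq2 and TMM scaling took it under the fold threshold (-0.81 and -0.83). In all, 24 genes were higher and 46 lower, with a highest adjusted p of 2.91e-05 (edgeR, Benjamini-Hochberg). TMM gave 25 higher and 15 lower and DESeq2 26 and 13, with the median of all genes raised by 0.28 and 0.30.

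Microglia- or macrophage-like cells showed the steepest folds between classes. FCGR1A (ENSG00000150337), the high-affinity receptor for IgG, was higher by 5.47 ± 0.05 on the log2 scale, with 1.99 ± 0.0689 transcripts per cell (SD, n = 2) against 0.0679 ± 0.00846 in astrocytes. ITGAX (ENSG00000140678), an integrin of myeloid cells, was higher by 5.42 ± 0.04 and P2RY13 (ENSG00000181631), a purinergic receptor, by 5.39 ± 0.04. Of 16 microglia and macrophage state genes 14 rose, also over the list alone, among them CD86, a costimulatory molecule (5.10 ± 0.05), GPR34, a lysophospholipid receptor (5.02 ± 0.05), and TREM2, a lipid-sensing receptor (4.93 ± 0.07). Of 7 lymphocyte-associated genes 4 rose, with the same count over the list alone: GPR183 (5.04 ± 0.05), CD4 (4.46 ± 0.04), CYTIP (4.04 ± 0.08) and FASLG (1.054 ± 0.15). FASLG had the lowest total of all panel genes, with 1383 counts on slide 1 and 1233 on slide 2, and fell under the fold threshold with TMM (0.67), DESeq2 (0.69), scaling to cell number (0.60) and Leiden resolution 2 (0.84). CD4 is also made by macrophages. CD52 of the same list was instead higher in excitatory neurons (1.02 ± 0.10, at 0.0648 ± 0.0118 per cell), but without the slide 2 excitatory sum it stood at 0.80. In all, 38 genes were higher and 5 lower, with a highest adjusted p of 7.42e-05 (edgeR, Benjamini-Hochberg). The split was 31 and 20 with TMM and with DESeq2 and 31 and 24 with scaling to cell number, which shifted the median of all genes by -0.39, -0.36 and -0.45.

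**Figure D2:**
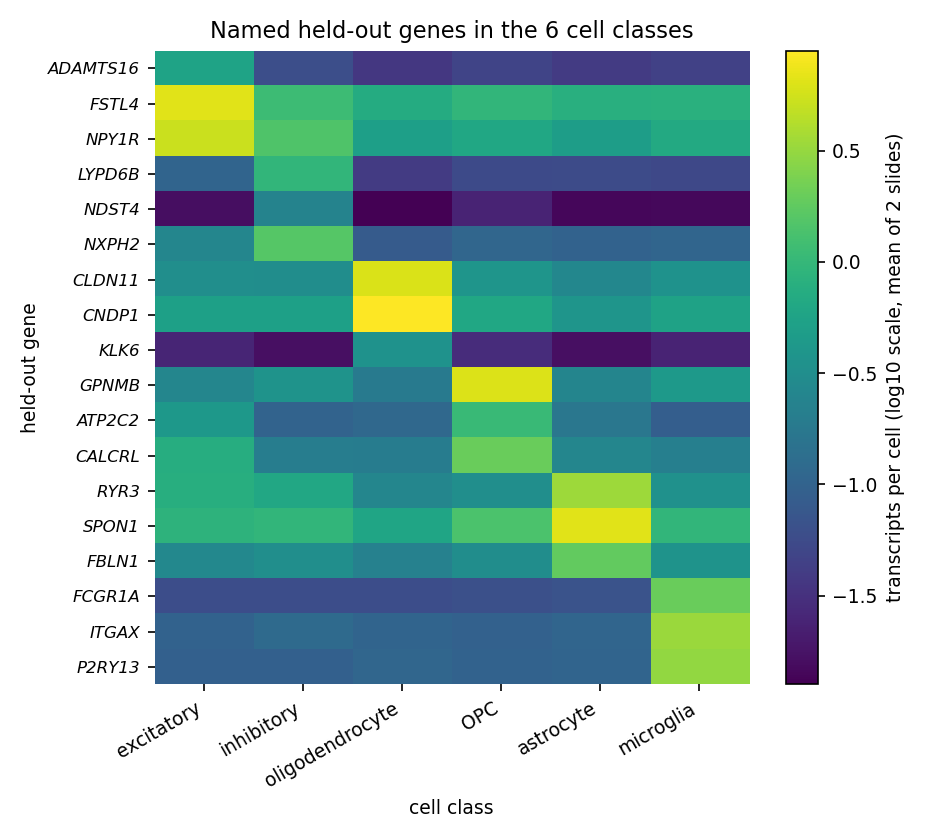
Transcripts per cell (colour, log10 scale, mean of both slides) of the 18 held-out genes named for the 6 classes, with genes down the side and classes along the bottom. Each gene is highest in the class it was named for; CNDP1 reached 8.91 transcripts per oligodendrocyte and GPNMB 6.23 per OPC-like cell.

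Excitatory neurons were compared by laminar subclass, since the blocks were picked to span the layers. Deep-layer-like cells, marked by THEMIS, HS3ST4, NR4A2 and NTNG2, were compared with the excitatory cells high in LAMP5 and CUX2, which are markers of superficial layers. These were 2 clusters of unlike make-up: the larger averaged 13.1 ± 0.121 LAMP5, 9.95 ± 1.00 CUX2 and 2.76 ± 0.139 RORB transcripts per cell (SD, n = 2), and the smaller, with RORB but neither LAMP5 nor CUX2 among its 10 leading genes, 6.59 ± 0.208, 10.2 ± 1.18 and 21.4 ± 2.41. NPFFR2 (ENSG00000056291), a receptor for neuropeptide FF, was higher in deep-layer-like cells by 6.33 ± 0.20 on the log2 scale, with 1.16 ± 0.0775 transcripts per cell (SD, n = 2) against 0.0175 ± 0.00227. HTR2C (ENSG00000147246), a serotonin receptor, was higher by 5.84 ± 0.19 (6.24 on slide 1 and 5.34 on slide 2, with 1.58 and 0.755 transcripts per cell), MCTP2 (ENSG00000140563), a membrane protein with calcium-binding domains, by 5.09 ± 0.18, SULF1 (ENSG00000137573) by 4.72 ± 0.18 and HS3ST2 (ENSG00000122254), a heparan sulfate sulfotransferase, by 4.33 ± 0.11. In the other direction THBS1 (ENSG00000137801), a thrombospondin, fell by 4.38 ± 0.19, PDGFD (ENSG00000170962), a platelet-derived growth factor, by 3.68 ± 0.18, LAMA2 (ENSG00000196569), a laminin chain, by 3.19 ± 0.17, NTNG1 (ENSG00000162631), a netrin-G axon guidance protein, by 2.73 ± 0.12, and IGFBP4 (ENSG00000141753), which binds insulin-like growth factors, by 2.20 ± 0.15. Taken against each of the 2 clusters apart, a comparison made after the results were seen and without a test, all 46 genes called higher were higher on both slides against each cluster, and at least 2-fold on both slides for 43 against the larger and 40 against the smaller. Of the 19 called lower, 17 were lower on both slides against each cluster, and at least 2-fold for only 13 and 11. PLCH1, called lower, was higher against the larger cluster (1.32 on slide 1 and 0.80 on slide 2) and lower against the smaller (-2.02 and -2.38), and TMEM132C changed sign between slides against the larger (0.18 and -0.31). PDGFD was lower against the larger (-4.33 and -4.56) and near equal against the smaller (0.15 and -0.22), TGFBI likewise (-2.24 and -2.62, against 0.45 and -0.23), and IGFBP4 was lower by less against the smaller (-2.64 and -2.97, against -0.27 and -0.85), while NTNG1 fell more against the smaller (-3.25 and -3.53, against -1.77 and -2.03).

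Matrix genes went both ways between these subclasses: 4 of 13 measured were higher in deep-layer-like cells and 4 lower, with the same counts over the list alone, and POSTN (4.22 ± 0.17) and ANXA1 (3.60 ± 0.17) stood among the higher ones. Of 10 synapse and excitability genes, KCNH5 was lower (-1.24 ± 0.10) and HTR2C higher. KCNH5 was lower by less against the larger cluster (-0.55 on slide 1 and -0.51 on slide 2) than against the smaller (-1.85 and -1.81). Genes of myelinating oligodendrocytes were higher in deep-layer-like than in LAMP5- and CUX2-high cells for 8 of 10, over the list alone as well, and for 2 of 10 against the other excitatory subclasses. CNDP1 reached 0.856 ± 0.130 transcripts per deep-layer-like cell against 8.91 ± 2.79 per oligodendrocyte, with a log2 difference of 1.56 ± 0.16 from LAMP5- and CUX2-high cells. In all, 46 genes were higher and 19 lower in deep-layer-like than in LAMP5- and CUX2-high cells, with a highest adjusted p among calls of 2.90e-10 (edgeR quasi-likelihood, Benjamini-Hochberg). Scaling to cell number gave 39 and 28 and shifted the median of all genes by -0.28, and DESeq2 shifted it by -0.12. These p-values rest on 2 residual degrees of freedom and a spread shared across genes, so they say little beyond the fold and its error.

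**Figure D3:**
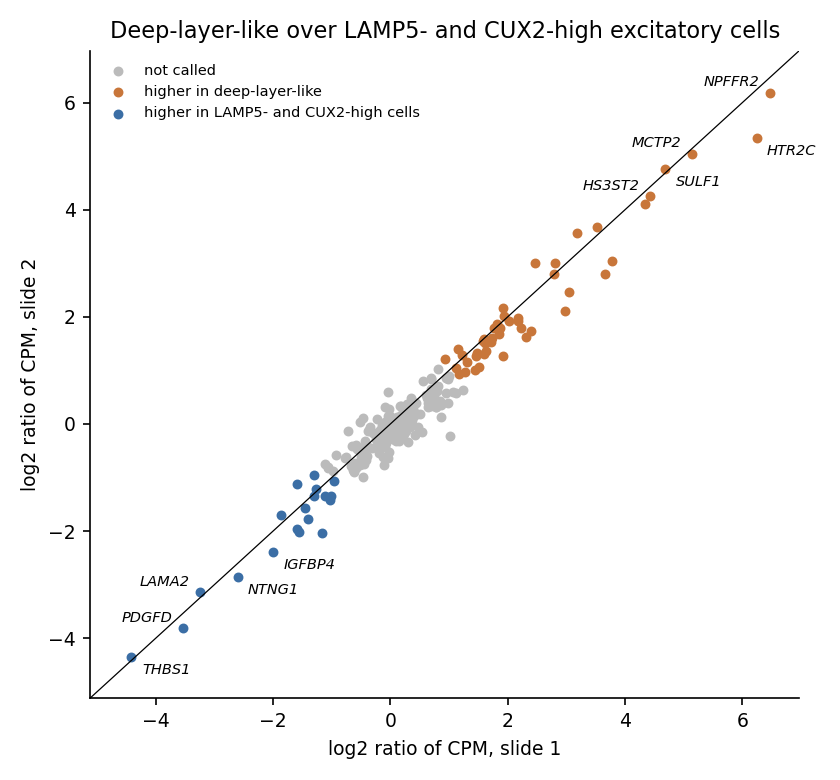
Log2 ratio of CPM in deep-layer-like over LAMP5- and CUX2-high excitatory cells on slide 1 (horizontal) and slide 2 (vertical); each point is 1 of 210 held-out genes, coloured by its call, and the line marks equal ratios. The 46 higher and 19 lower genes had the same sign on both slides, from NPFFR2 at 6.47 and 6.19 to THBS1 at -4.42 and -4.36.

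Against the mean of the other excitatory subclasses, deep-layer-like cells had 39 genes higher and 20 lower, led by MCTP2 (4.84 ± 0.13), HTR2C (4.70 ± 0.14, with 5.29 on slide 1 and 4.07 on slide 2) and NPFFR2 (4.42 ± 0.14). Another cluster is called TSHZ2- and RORB-led after its markers. TSHZ2 was its first gene by fold, while RORB, a transcription factor of layer-specific neurons, came after CENPF, RXFP1 and HS3ST2. RORB averaged 20.6 ± 2.06 transcripts per cell there, against 21.4 ± 2.41 in the smaller LAMP5- and CUX2-high cluster. The TSHZ2- and RORB-led cluster had 16 higher and 22 lower, and 13 and 31 with scaling to cell number, which shifted the median by -0.24. Its named genes were CENPF (2.61 ± 0.13), LYPD6B (2.58 ± 0.13) and PLCH1 (ENSG00000114805), a phospholipase C (2.46 ± 0.09). CENPF encodes a kinetochore protein of dividing cells and stood at 0.922 ± 0.0716 transcripts per cell here against 0.436 ± 0.160 in deep-layer-like cells. LAMP5- and CUX2-high cells, summed over both clusters, had 14 higher and 43 lower, and 23 and 29 with scaling to cell number, which raised the median by 0.33. PDGFD (4.03 ± 0.14), THBS1 (3.76 ± 0.14) and LAMA2 (2.56 ± 0.13) led them. The share of excitatory cells that were deep-layer-like was 9.25% on slide 1 and 23.1% on slide 2 (16.2% ± 9.80, SD, n = 2), the LAMP5- and CUX2-high share 71.9% and 55.5%, with the RORB-high smaller cluster counted in it (5.02% and 4.07% of all cells, beside 8.60% and 7.03% for the larger), and the TSHZ2- and RORB-led share 18.9% and 21.4%.

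Named inhibitory neurons split into 4 subclasses of similar size, whose shares of inhibitory cells differed by under 2 points between slides. These shares leave out the unnamed cluster led by RELN, CXCL14 and VIP, with 2.35% of all cells on slide 1 and 1.53% on slide 2. PVALB-like cells, the fast-spiking interneurons, made up 24.5% and 25.8%, SST-like cells, which express somatostatin, 27.5% and 27.7%, LAMP5-like cells 23.4% and 23.5%, and the cluster led by VIP 24.6% and 23.0%. In PVALB-like cells, MEPE (ENSG00000152595), a matrix phosphoglycoprotein known from bone, was higher by 5.02 ± 0.12 on the log2 scale, with 2.32 ± 0.603 transcripts per cell (SD, n = 2) against 0.0791 ± 0.0114 in SST-like cells. SULF1 was higher there by 4.34 ± 0.05 (6.09 ± 0.326 per cell) and POSTN (ENSG00000133110) by 4.12 ± 0.08 (1.17 ± 0.140 per cell). SST-like cells were marked by COL25A1 (ENSG00000188517), a membrane collagen (3.35 ± 0.05), CHODL (ENSG00000154645), a C-type lectin known from these neurons (2.78 ± 0.16), and CDH1 (ENSG00000039068), the epithelial cadherin (2.75 ± 0.09); CHODL was rare, at 0.143 ± 0.0309 per cell, and on slide 2 its total lay under that of the brightest control probe. LAMP5-like cells had higher PDGFD (2.97 ± 0.06), EYA4 (ENSG00000112319), a transcriptional coactivator (2.64 ± 0.07), and NR2F2 (ENSG00000185551), a nuclear receptor (2.07 ± 0.04), which was as abundant in the VIP-led cluster (2.48 ± 0.0894 against 2.50 ± 0.0256 per cell). Among the 4 measured progenitor genes, EGFR rose in LAMP5-like cells (2.07 ± 0.03) and in the VIP-led cluster (1.502 ± 0.03) and was lower in PVALB-like (-1.99 ± 0.04) and SST-like cells (-1.58 ± 0.04). The VIP-led cluster had higher RGS16 (ENSG00000143333), a regulator of G protein signalling (3.23 ± 0.04), MCTP2 (2.69 ± 0.07) and HTR2C (2.43 ± 0.06).

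The matrix list again split by subclass: 4 of 13 were higher and 3 lower in PVALB-like cells, 3 higher and 2 lower in LAMP5-like cells and in the VIP-led cluster, and 0 higher and 2 lower in SST-like cells, each with the same counts over the list alone. The SST-like genes were COL12A1 (-2.49 ± 0.07) and IGFBP3 (-1.003 ± 0.04), and IGFBP3 fell short of the fold threshold at Leiden resolution 2 (-0.99) and without the slide 2 SST-like sum (-0.98). Over all held-out genes, LAMP5-like cells had 22 higher and 29 lower, PVALB-like 32 and 25, SST-like 18 and 15, and the VIP-led cluster 20 and 25. The highest adjusted p among these calls was 0.00200 in LAMP5-like cells (edgeR quasi-likelihood, Benjamini-Hochberg). LAMP5-like cells had 24 and 21 with TMM and with DESeq2. The SST-like split turned to 14 and 25 with TMM and with DESeq2, which moved the median of all genes by -0.22 and -0.23, and to 15 and 24 with scaling to cell number (-0.19). PVALB-like cells had 39 and 16 with scaling to cell number, with the median raised by 0.31, and their median rose by 0.11 and 0.17 with TMM and DESeq2.

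The slides were compared because adjacent sections of 2 donors lay on both. Over all cells the slides were close, with a median absolute log2 ratio of CPM of 0.08 over 266 genes. NPFFR2 was the 1 gene at least 1.5-fold apart, with 181 CPM on slide 1 and 327 on slide 2, a ratio of 1.81 (95% interval 1.76 to 1.85). THEMIS, a marker of deep layers here (1.499, 1.474 to 1.524), MCTP2 (1.49, 1.46 to 1.51), MOBP, a myelin protein (1.39, 1.38 to 1.39), and ROS1 (ENSG00000047936), a receptor tyrosine kinase (1.379, 1.362 to 1.396), followed on slide 2. Higher on slide 1 were THBS1 (1.38-fold, 1.36 to 1.39), KLF4 (ENSG00000136826), a transcription factor of endothelial and other cells (1.36, 1.33 to 1.38), SLC26A4 (ENSG00000091137), an anion exchanger (1.35, 1.34 to 1.37), NTNG1 (1.29, 1.29 to 1.30) and P2RY12 (1.27, 1.26 to 1.28). These intervals cover counting error only and exclude a ratio of 1, but with 1 library per slide no difference was tested.

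Within classes, more genes were 1.5-fold apart than over all cells. Excitatory neurons had 11 higher on slide 2 and 3 on slide 1, astrocytes and OPC-like cells 4 and 3, oligodendrocytes 3 and 0, inhibitory neurons 2 and 0, and microglia- or macrophage-like cells 1 and 1. Among genes with at least 1000 transcripts in the class these became 2 and 0 in OPC-like cells and 2 and 0 in oligodendrocytes, and the other 4 pairs stayed as they were. These counts include shifts between the clusters of a class. The SERPINA3-led astrocytes went from 2.35% to 4.36% of cells and the WIF1-led ones from 7.36% to 5.77%, and NPFFR2 was 1.76-fold higher on slide 2 in astrocytes but 1.27-fold and 0.884-fold within those 2 clusters. In excitatory neurons it was 2.30-fold higher on slide 2 and 1.102-fold within the larger deep-layer-like cluster, and MCTP2 was 2.03-fold and 1.01-fold. That cluster itself differed between slides, with 21 genes higher on slide 1 and 1 on slide 2 (11 and 0 among genes with at least 1000 transcripts) and medians of 474 and 346 transcripts per cell. Deep-layer-like cells made up 1.75% of all cells on slide 1 and 4.62% on slide 2, a ratio of 2.64. These shares, and the shares of excitatory cells above, leave out the unnamed cluster led by MOG, HS3ST2 and CAPN3.

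Non-negative factors carried over between slides with little loss. At rank 20, factors fitted on slide 1 explained 72.8% of the sum of squares on slide 2, where slide 2's own factors explained 73.1%; factors from slide 2 explained 74.9% on slide 1, against 75.2% for its own. A single factor explained 52.1% on slide 1 and 49.7% on slide 2, and slide 1 factors with shuffled genes explained 22.9% on slide 2. Of 20 factors, 15 were matched at a cosine of 0.8 or more, with a median cosine of 0.976, and 0 were matched after shuffling. At a cosine of 0.9 or more, 11 of 20 were matched. At rank 10 all 10 were matched at 0.8 and at rank 30 it was 20 of 30, with a median cosine of 0.906, a lowest of 0.00925 and 1 match after shuffling. Counts without log gave 19 of 20. The best match was a myelin factor of CNDP1, UGT8 and CLDN11 (cosine 0.998), highest in oligodendrocytes, followed by factors led by SST and SYNPR (0.997), by CX3CR1 and P2RY12 in microglia (0.996), and by PDGFRA and VCAN in OPC-like cells (0.995). The 5 unmatched factors were led on slide 1 by TESPA1 and CCK (0.759), LAMP5 and MEIS2 (0.755), WIF1 and SPON1 (0.747), GJA1 and APOE (0.667), and IDH2 and CUX2 (0.441), genes of excitatory neurons and astrocytes for the most part. For 19 of 20 slide 1 factors, the cell group with the highest mean weight on slide 1 stayed the same when that factor was carried to slide 2. The weights of the paired slide 2 factors were not compared.

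**Figure D4:**
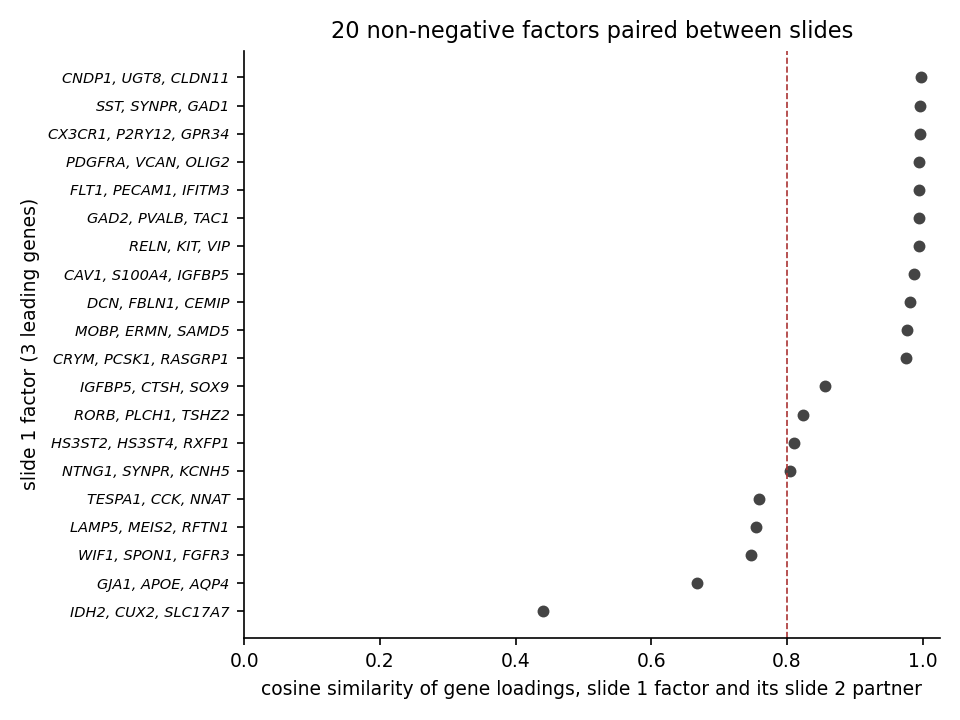
Cosine similarity of gene loadings between each of 20 slide 1 factors and its slide 2 partner (horizontal axis, from 0), with factors named by their 3 leading genes and a dashed line at 0.8. Of 20 factors, 15 lie at or right of the line, from 0.998 for the CNDP1 factor down to 0.441 for the IDH2 factor.

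Background was low beside gene counts. The 20 negative control probes averaged 1305 counts each on slide 1 and 1404 on slide 2, against 215442 and 181142 per gene. A single probe held 22.01% of control probe counts on slide 1 and 28.0% on slide 2. Negative control codewords summed to 2011 and 1449 counts, and unassigned codewords averaged 1006 and 811 each. FASLG was the lowest gene, and on slide 2 FASLG (1233 counts) and TOP2A (1404) did not exceed the mean control probe. In all, 12 genes on slide 1 and 19 on slide 2 had fewer counts than the brightest control probe. Among them were TOP2A, MKI67, CCNB2, CD2, IL7R and ADAMTS12 on both slides and CD52, GPR183 and GZMA on slide 2. Summed over all 20, control probes ranged from 281 CPM of panel transcripts in excitatory neurons to 693 over the classes on slide 1. On slide 2 this sum ranged from 363 to 906.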

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

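The test of deprecated codewords by the class in which control probes were lowest was chosen only after the result was seen.

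Deprecated codewords, barcodes withdrawn from a panel and assigned to no gene here, lay far above the negative controls on both slides: the 7 averaged 158729 counts each on slide 1 and 127184 on slide 2, which is 122 and 90.6 times the mean of 1305 and 1404 counts per negative control probe, and they held 1.89% and 1.81% of all counts. Background as the control probes measure it argues poorly for them. On both slides 6 of the 7 were highest in excitatory neurons, where control probes were lowest. Deprecated counts ran from 9548 to 37304 CPM of panel transcripts over the classes on slide 1 and from 9062 to 35087 on slide 2. Unassigned codewords went the same way. On slides 1 and 2 they were highest in excitatory neurons (5094 and 4929 CPM) and lowest in astrocytes (1995 and 1929). They averaged only 1006 and 811 counts each. Negative control codewords did not, and were highest in oligodendrocytes (51.9 and 47.1 CPM). The class pattern therefore does not exclude background shared with unassigned codewords. The planned test had asked whether a codeword's range over the classes was over double that of the control probes, which held for 1 codeword only, the outcome set in advance for background. That bound was a poor one, because the control probes varied 2.46-fold and 2.49-fold in CPM, in the opposite direction, and most of this came from dividing by panel transcripts: per 100 cells the probes ran only from 15.5 to 20.9 counts on slide 1 and from 17.1 to 23.4 on slide 2, again lowest in excitatory neurons, where deprecated codewords reached 2057 and 1650 against 365 and 245 in the lowest class. Misreading of 1 panel gene's codeword was also tested, and for 0 codewords did the same gene reach r = 0.99 over the clusters on both slides, the closest being C1QL3 at 0.982 and 0.980. No biological explanation was tested; transcripts of genes dropped from the panel stay a candidate explanation that the sources used here do not settle.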

How the results depend on the processing

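Leiden seeds 2 and 3 were chosen only after the results were seen; the other alternatives were planned. A count is said here to move when it changes by over 1.5 times, and a share when it changes by 1 SD between slides or more. Of 413 alternative values of the main results 393 stayed within these limits and 20 moved, and the cause was not tested beyond what each setting changes by construction. Of 63 alternative shares of single classes and of cells without a class name 16 moved, and of 56 alternative counts in the fits of the FLT1- and PECAM1-led and astrocyte clusters 8. Shares taken from 1 slide alone could not move, because 1 of 2 slides always lies under 1 SD from their mean. Such shares are counted among the 63, among the 413 and among the 34 below. Leaving off the filter on low counts could change little either, because all 210 held-out genes had passed it. Its values are counted among the 413, the 33 counts and the 168 sets of calls below. Scaling to cell number, which adds differences in total per cell, gave among lower genes 19 in excitatory neurons, 14 in inhibitory neurons, 95 in oligodendrocytes, 24 in microglia- or macrophage-like cells, 16 in PVALB-like and 24 in SST-like cells, and 23 higher in LAMP5- and CUX2-high cells. TMM gave 4 lower in OPC-like cells, 15 in astrocytes, 20 in microglia- or macrophage-like and 25 in SST-like cells, and DESeq2 gave 13, 20 and 25 in the last 3. Lower genes in OPC-like cells numbered 5 at Leiden resolution 2 and 6 with seed 2 and with seed 3. Clustering on all panel genes put the inhibitory share of neurons at 47.1%, the excitatory neuron-like share of cells at 10.8% and the share without a class name at 45.2%. Between slides, transcripts per cell gave 4 genes at least 1.5-fold apart in place of 1, with 1 higher on slide 2 and 3 on slide 1, and a threshold of 2-fold gave 0. Dropping the slide as a replicate block, or the filter on low counts, changed none of the 33 counts by over 1.5 times, and leaving out either slide of a class none of 34, but smaller changes occurred: without the block the TSHZ2- and RORB-led cells had 17 higher in place of 16, and without slide 2 the SST-like cells had 19 higher and 20 lower in place of 18 and 15, and the OPC-like cells 7 lower in place of 10. The larger of the higher and lower counts changed side in astrocytes (24 and 46, but 25 and 15 with TMM and 26 and 13 with DESeq2), oligodendrocytes (18 and 26, but 22 and 21 with DESeq2), LAMP5-like cells (22 and 29, but 24 and 21 with TMM and with DESeq2), SST-like cells (18 and 15, but 14 and 25 with TMM and with DESeq2, 15 and 24 with scaling to cell number and 19 and 20 without slide 2), TSHZ2- and RORB-led cells (16 and 22, but 21 and 19 with k-means) and excitatory neurons (61 and 59, but 57 and 60 without slide 2). Over 168 alternative sets of calls, the median share of calls kept was 98.1%, with a lowest of 52.9% in astrocytes under DESeq2. Clustering on all panel genes and the filter of 10 transcripts per cell are not among these sets. Genes were not tested again under those 2 settings, so only their shares of cells were compared. The rarest genes lay near background: 12 genes on slide 1 and 19 on slide 2 had fewer counts than the brightest control probe. That probe itself had 5744 counts on slide 1 and 7867 on slide 2.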

Other observations

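The test of deep-layer genes summed over all cells, the test of median transcripts per cell in the astrocyte clusters, the fits of the cluster led by FLT1 and PECAM1 and of the astrocyte clusters, and Leiden seeds 2 and 3 were chosen only after the result was seen.

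The largest cluster without a class name was led by FLT1 and PECAM1, with NKG7 also among its 10 leading genes. KLF4 was higher there by 4.97 ± 0.06 on the log2 scale, KLF2 (ENSG00000127528), a transcription factor that responds to blood flow, by 4.72 ± 0.04 and CAV1 (ENSG00000105974), the coat protein of caveolae, by 4.40 ± 0.04, with 1.70 ± 0.0387 transcripts per cell (SD, n = 2) against 0.170 ± 0.00394 in OPC-like cells. Of 13 matrix genes 7 rose, also adjusted over the list alone, and NES (2.34 ± 0.03) and HES1 (2.26 ± 0.08) rose with them. Of 16 microglia and macrophage state genes 4 rose, among them CD163 (2.28 ± 0.07) and LYVE1 (1.87 ± 0.04), a share near the 48 of 210 over all held-out genes. Of 7 lymphocyte-associated genes 4 rose, CD4 (1.85 ± 0.04), CD52, CYTIP and FASLG. CD52 on slide 2 and FASLG on both slides had fewer counts than the brightest control probe. CD163, LYVE1 and CD4 are genes of perivascular macrophages, but most of the microglia and macrophage list was not called higher. In all, 48 genes were higher and 4 lower than in the mean of the 6 classes, with a highest adjusted p of 2.17e-06 (edgeR, Benjamini-Hochberg). The split was 45 and 18 with TMM, 44 and 21 with DESeq2 and 40 and 32 with scaling to cell number, which shifted the median of all genes by -0.36, -0.41 and -0.55.

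Astrocytes fell into 3 clusters led by WIF1, SERPINA3 and SFRP2. Transcripts of neighbouring neurons assigned to these cells were not tested as a source of the neuronal genes named here. The WIF1-led cluster had 30 genes higher and 22 lower than the others, led by SLC17A6 (ENSG00000091664), a glutamate transporter (2.03 ± 0.09), SNCG (ENSG00000173267), a synuclein (1.89 ± 0.08), and WIF1 at 14.9 ± 0.163 transcripts per cell (SD, n = 2) against 4.96 ± 1.99 in the SERPINA3-led cluster (1.86 ± 0.10 on the log2 scale). The SERPINA3-led cluster had 38 higher and 5 lower, led by HS3ST2 (3.97 ± 0.09), NPFFR2 (3.69 ± 0.13) and RXFP1 (ENSG00000171509), a relaxin receptor (2.93 ± 0.08), all 3 also higher in deep-layer-like than in LAMP5- and CUX2-high cells; SERPINA3, an acute-phase protease inhibitor of reactive astrocytes, rose by 2.45 ± 0.12, and the cluster held 2.35% of cells on slide 1 and 4.36% on slide 2. The SFRP2-led cluster had 17 higher and 58 lower, with SFRP2 (ENSG00000145423), a Wnt antagonist, at 4.15 ± 0.08, PLCE1 (ENSG00000138193), a phospholipase, at 2.89 ± 0.08, IGFBP5 (ENSG00000115461) at 2.75 ± 0.06 and NES at 1.47 ± 0.07. The highest adjusted p among these calls was 5.70e-05 (edgeR, Benjamini-Hochberg). Scaling to cell number gave 59 and 10 in the WIF1-led cluster, with the median of all genes raised by 0.51, and DESeq2 gave 33 and 15 (0.11). DESeq2 gave 29 and 10 in the SERPINA3-led cluster (-0.23), where TMM and scaling to cell number moved the median by -0.17 and -0.18. TMM gave 25 and 47 in the SFRP2-led cluster (0.21), where DESeq2 and scaling to cell number moved the median by 0.12 and -0.32.

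Deep-layer-like cells made up 2.64 times as large a share of cells on slide 2 as on slide 1, and between 2.47 and 2.89 times over 7 alternative clusterings and filters and the reported one. In the reported clustering the unnamed cluster led by MOG, HS3ST2 and CAPN3, with 11.5% and 11.7% of cells, is not counted. HS3ST2, HTR2C, RXFP1 and POSTN, among its 10 leading genes, were all called higher in deep-layer-like than in LAMP5- and CUX2-high cells. The ratio of 2.64 therefore depends on leaving that cluster out. An even loss of depth on slide 2 argues poorly for the larger share there. Slide 1 cells were thinned to 82.4% of their transcripts, to the median of slide 2. Their deep-layer-like share was then 2.08% against 1.91% unthinned, a ratio of 1.09. The thinning took the same fraction from each cell, while the larger deep-layer-like cluster had medians of 474 and 346 transcripts per cell. An uneven loss of depth was not tested. Assignment of transcripts to the wrong cells on slide 2 could not be settled, because the 39 held-out genes called higher in deep-layer-like cells had a median CPM ratio of 1.099 (slide 2 over slide 1) over all cells, just under the bound of 1.1 set to exclude it, with 31 of 39 above 1 against 95 of the other 227 panel genes. The donors and the stretch of cortex on each slide stay open and cannot be told apart from the slide, and no biological explanation was tested. Differences in the clusters' shares of panel transcripts accounted for 52.9% of the sum of squared log2 ratios between slides over the panel. These shares depend on transcripts per cell as well as on numbers of cells.

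Genes of neurons and of myelin differed between the astrocyte clusters. Of 10 synapse and excitability genes 9 were lower in the SFRP2-led cluster and 6 higher in the WIF1-led cluster, and of 10 myelinating oligodendrocyte genes 8 were higher in the SERPINA3-led cluster and 4 lower in the SFRP2-led one, also adjusted over the list alone. Depth was not tested for the neuronal genes, where WIF1-led cells had medians of 420 transcripts on slide 1 and 385 on slide 2. Assignment of transcripts from neighbouring neurons was not tested for them either. SLC17A6 and SNCG averaged 0.692 ± 0.0403 and 0.958 ± 0.0182 transcripts per WIF1-led cell (SD, n = 2). Over all astrocytes, SLC17A7 stood at 31.9% of its level in excitatory neurons. Fewer transcripts per SFRP2-led cell argue poorly for the myelin difference. The SERPINA3-led and SFRP2-led clusters had medians of 309 and 269 transcripts per cell on slide 1 and 247 and 266 on slide 2, ratios of 0.871 and 1.08. Genes called higher in oligodendrocytes differed between them by a median CPM ratio of 2.11 (2.17 on slide 1 and 2.10 on slide 2). Transcripts of neighbouring oligodendrocytes assigned to SERPINA3-led cells are a candidate explanation: 17 of 18 such genes had an excess over the SFRP2-led cluster, with a median of 7.78% of the oligodendrocyte level. The 18 count SERPINA3 itself, at 190% of that level, more than oligodendrocyte transcripts can give, and GZMA at 92.0%. The quartiles, 4.27% and 16.2%, lay 3.78-fold apart, between the bounds of 3-fold and 6-fold set for and against a single source, so the 2 readings cannot be told apart here.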
